A study of Solanum lycopersicum with 6 samples.

How the data were processed

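RNA from pericarp of WT and JMJ6-OE tomato fruit at 37 days after anthesis was sequenced on an Illumina HiSeq 2000 from mRNA libraries, per the labels. Each genotype has 3 libraries, taken to their groups by their sample titles. HISAT2 is the tool named in the submitters' processing notes. Its version, the read counter, the genome build, the annotation and the strandedness of counting are not given in the sources used here.

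One deposited table of 36224 rows gives, per the file headers, the authors' raw count per gene and library, the authors' FPKM per gene and library, and the authors' comparison of the groups. Of the rows, 35768 carry tomato gene identifiers and 456 carry MSTRG identifiers, the default name of loci assembled from reads. The MSTRG loci held at most 0.38% of a library's counts. The deposited log2 fold column equals the log2 ratio of the groups' mean FPKM, checked on all rows, with a mean of 0 set to 0.001. The authors' p-value and false discovery rate columns come from a test not given in the sources used here. The deposited FPKM values were used only for these checks and for the implied gene length, and symbols, descriptions and pathways are those of the deposited table.

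Deposited counts were used as they stand, with totals of 28539410 to 36487547 per library. A floor of 3 counts is 0.082 to 0.11 CPM, and floors and counting intervals cover counting error only. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 20143. Libraries were scaled by TMM, and JMJ6-OE was tested against WT in a model of genotype alone by the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The standard error is the absolute log2 fold change divided by the root of the test's F. CPM values are on the TMM-scaled library sizes. The common biological coefficient of variation was 0.21. Replicate pairs differed by 19.2 to 71.8 times the sampling noise in a chi-square of their counts, so no library is a copy of another.

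Before the data were examined, 23 gene lists, the test design, the alternatives and the rule for named genes were fixed. The rule named the tested JmjC-domain genes, up to 4 called members of each list by adjusted p, and 12 ripening genes, whether called or not. It also named up to 8 genes each with the largest increase and decrease among called genes with a mean of at least 10 CPM over all libraries, no overlap between the groups and a symbol or informative description. Camera tests on voom values (limma 3.58.1) compared each list with all other tested genes at a preset inter-gene correlation of 0.01. Camera was repeated with an estimated correlation, which also bases the test's degrees of freedom on the libraries instead of the genes. Fry tested whether a list's genes moved one way. Annotated pathways with 5 to 300 tested members were tested in the same way. One listed identifier each for ethylene biosynthesis and sugar metabolism had no row. Further, 2 members were removed because the table describes them as other proteins than the list meant, one each from the cell wall softening and carotenoid lists.

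The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library in turn. The functions were tested on simulated counts for JMJ6-OE against WT. These were drawn from the real means, library sizes and the trend of dispersion with expression, with a few genes changed 1.5-fold, 2-fold or 4-fold. Of the simulated genes, 19883 passed the filter. In this setting edgeR recovered 87.9% of 66 genes changed 4-fold, 56.7% of 67 changed 2-fold and 13.4% of 67 changed 1.5-fold, with 4 false calls. In the data 34.3% of genes were called, where the adjustment is less strict, so these shares do not give the power there. In a simulation of 20143 genes, camera called a set of 40 genes changed 2-fold and 0 of 20 unchanged sets. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. Figures were drawn with matplotlib 3.10.9.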

Results

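The transcriptome of tomato fruit wall (pericarp, cultivar Ailsa Craig) was profiled by RNA sequencing in wild-type (WT) fruit and in fruit of transgenic plants that overexpress the histone demethylase SlJMJ6 (JMJ6-OE), all taken at 37 days after anthesis. Each genotype was represented by 3 libraries. The WT libraries held 28539410, 36487547 and 36237783 counts and the JMJ6-OE libraries 32218345, 36299263 and 30508225, and 22118 to 23165 genes had at least 1 count per library. In a principal component analysis of log2 CPM (counts scaled to a library of 1e+06), the first component held 70.1% of the variance and separated all WT from all JMJ6-OE libraries. The second held 9.9% and mainly spread the JMJ6-OE libraries, from 50.4 in replicate 1 to -43.6 in replicate 3. The labels do not say whether replicates came from separate plants or separate transgenic lines, so p-values measure the spread between these libraries.

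**Figure D1:**
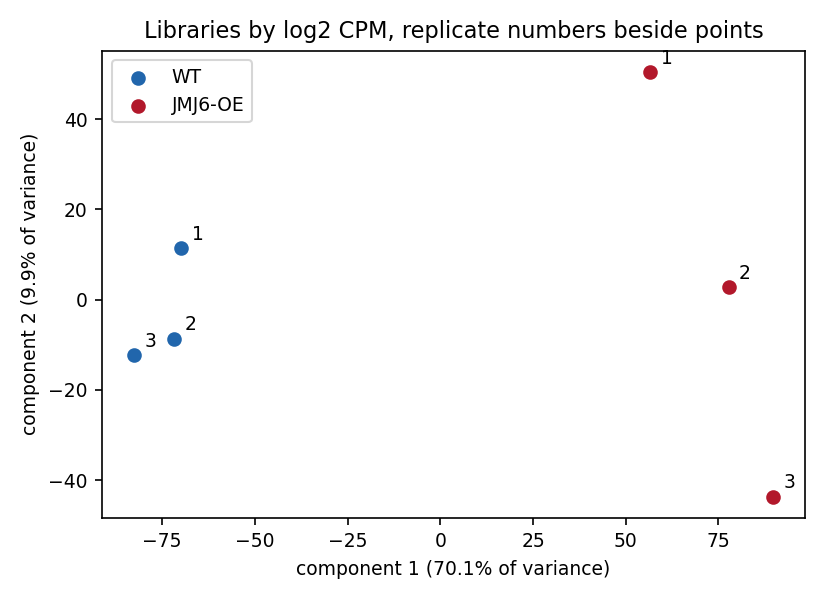
Positions of the 6 libraries on the first and second principal components of log2 CPM over the 20143 tested genes, with replicate numbers beside the points. WT libraries lie between -82.5 and -69.8 on the first component and JMJ6-OE libraries between 56.7 and 89.7.

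The comparison of JMJ6-OE with WT asks which transcripts change when this demethylase, which the study's title links to removal of H3K27 methylation, is overexpressed. At the same fruit age, JMJ6-OE pericarp held more transcript of many ripening genes. For the genes called, a response to the demethylase and a difference in ripening stage therefore cannot be told apart. Transcript of polygalacturonase PG2A, which degrades pectin, averaged 44.6 ± 7.06 CPM in WT and 4345 ± 663 CPM in JMJ6-OE (mean ± SD, n = 3). Transcript of phytoene synthase PSY1, the entry enzyme of carotenoid synthesis, averaged 410.4 ± 111 and 5212 ± 1452 CPM, and that of the ripening regulator RIN 44.2 ± 19.8 and 462 ± 151 CPM. Many genes of the photosystems and many ethylene response factors were lower in JMJ6-OE, with 53 of 78 and 32 of 62 tested members called. By edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment at 0.05, 3517 of 20143 tested genes were higher in JMJ6-OE and 3394 were lower. At least a 2-fold difference was found for 1163 of the higher and 1806 of the lower genes. The groups did not overlap in CPM for 51.4% of the tested genes, where chance gives 10%. Without JMJ6-OE replicate 2, 2027 genes were higher and 2046 lower, and without WT replicate 2, 2296 genes were higher.

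The reference gene table used here, of assembly SLM_r2.1, names 1 gene JMJ6, on chromosome 6 beside a cluster of Mi-1 resistance genes. Of the 24 rows of the deposited table described as JmjC-domain (histone demethylase) genes, only Solyc06g008490.3 lies on chromosome 6, and 4 rows within 10 positions of it are described as resistance proteins. It was taken as JMJ6 by this neighbourhood, since the identifiers are not paired directly. The deposited table describes it as a putative JMJ16 demethylase, and only 1 reference neighbour was found by its locus name, so the match is uncertain. Its transcript was 27.0, 23.5 and 25.5 CPM in the WT libraries and 31.5, 37.4 and 41.3 CPM in the JMJ6-OE libraries, a log2 fold change of 0.54 ± 0.12 (SE) with an adjusted p of 0.014. This 1.45-fold increase lost its call without JMJ6-OE replicate 2 (adjusted p = 0.055) or WT replicate 2 (adjusted p = 0.054).

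Of the 20 tested JmjC genes, 4 rose, 2 fell and 14 did not pass the test, with the same counts when adjusted over the list alone (4 and 2). Besides JMJ6, the genes that rose were REF6 (Solyc03g111590.3, log2 fold change 0.27 ± 0.07), a JMJ25 gene (Solyc02g078790.3, 0.29 ± 0.08) and a JMJ706-like gene at only 1.13 ± 0.160 CPM in JMJ6-OE (Solyc03g097090.3, 1.05 ± 0.31). Those that fell were the gene described as JMJ524 (Solyc01g006680.3, -0.48 ± 0.09) and a JMJ25-like gene (Solyc08g065820.2, -0.59 ± 0.18). Only the JMJ524 call held in every fit that left out 1 library. The others were lost in several, with adjusted p up to 0.13 for REF6 (without WT replicate 3), 0.11 and 0.14 for the JMJ25 and JMJ706-like genes that rose (without JMJ6-OE replicate 2) and 0.092 for the JMJ25-like gene that fell (without WT replicate 1). One ELF6-like gene (Solyc04g028580.2) stood at 21 CPM in JMJ6-OE replicate 1 and at 6.06 and 4.08 CPM in replicates 2 and 3, against 5.93 ± 0.339 CPM in WT, and was not called (log2 fold change 0.81 ± 0.60, adjusted p = 0.34, and -0.22 without JMJ6-OE replicate 1).

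The remaining JmjC genes, none called, of which a JMJ25 gene (Solyc02g082400.3, adjusted p = 0.068) was called with upper-quartile scaling (adjusted p = 0.026), had log2 fold changes from -0.66 for the JMJ14 gene to 0.34 for the Jmjd7 gene. Of the 9 tested genes of Polycomb repressive complex 2, which places the H3K27 methylation, 3 fell and none rose, also when adjusted over the list alone (3). They were a CURLY LEAF gene (Solyc03g044380.3, EZ2, -0.71 ± 0.17), MSI1 (Solyc11g020290.2, -0.48 ± 0.14) and a gene described as EZ1 (Solyc01g079390.3, -0.35 ± 0.10). Each of these calls was lost in at least 3 of the 6 fits that left out a library, with adjusted p up to 0.062, 0.12 and 0.14, in each case without JMJ6-OE replicate 2. The median log2 fold change of the Polycomb list was 0.013 and its mean -0.15. The camera test found no shift of either list against other genes (adjusted p = 0.68 for JmjC genes and 0.55 for Polycomb).

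Of 17 ripening regulators, 10 rose, 4 fell and 3 did not pass, or 12 and 4 adjusted over the list alone. RIN, a MADS-box regulator of ripening, had a log2 fold change of 3.38 ± 0.45 (adjusted p = 0.0032). FUL1/TDR4, another MADS-box gene, rose by 2.41 ± 0.20 and the pigment regulator APRR2 by 1.72 ± 0.16. The NAC gene NOR rose by 1.33 ± 0.29, a call lost without JMJ6-OE replicate 2 (adjusted p = 0.051). CNR rose by 1.13 ± 0.20, TAGL1 by 0.84 ± 0.12 and the DNA demethylase DML2 by 1.43 ± 0.23, from 731 ± 85.1 to 1969 ± 538 CPM. MADS1, known as a repressor of ripening, had a log2 fold change of -0.96 ± 0.14. The list shifted upward in the camera test (adjusted p = 0.029), which did not hold with an inter-gene correlation estimated from the data (adjusted p = 0.70 with an estimated correlation).

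**Figure D2:**
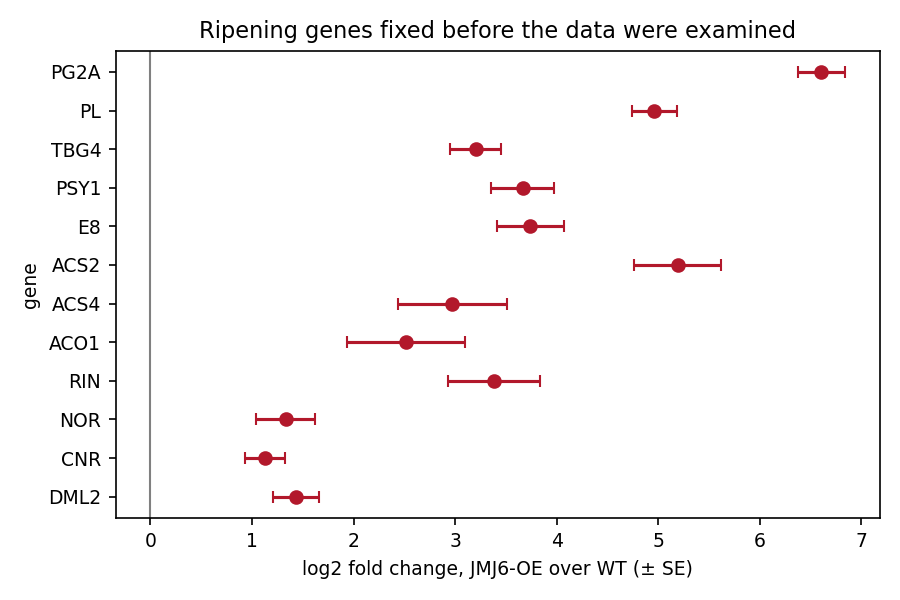
Log2 fold change of JMJ6-OE over WT, with the standard error of the edgeR fit, for the 12 ripening genes named by rule before the data were examined (3 libraries per genotype). All lie above 0, from 1.13 for CNR to 6.61 for PG2A.

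In ethylene synthesis, ACS2, which makes the ethylene precursor in ripening fruit, stood at 8.49 ± 3.54 CPM in WT and 312 ± 106 CPM in JMJ6-OE (log2 fold change 5.19 ± 0.43, adjusted p = 6.1e-04). ACS4 rose by 2.97 ± 0.54 (3.73 without WT replicate 2) and the ethylene-regulated gene E8 by 3.74 ± 0.33. SAM3 rose by 0.58 ± 0.12, not called without WT replicate 2 (adjusted p = 0.052). ACO1, the enzyme of the last step, rose by 2.52 ± 0.58 (3.22 without WT replicate 3). Its call was lost without JMJ6-OE replicate 2 (adjusted p = 0.056), JMJ6-OE replicate 3 (0.062) or WT replicate 2 (0.070). In all, 5 of 13 tested genes rose and 1 fell, with the same counts adjusted over the list alone, and camera gave an adjusted p of 0.079 (0.044 without WT replicate 2, 0.030 without WT replicate 3, 0.040 with no filter and 0.025 with the replicate block, but adjusted p = 0.63 with an estimated correlation). Of 19 perception and signalling genes, 6 rose and 4 fell (6 and 5 adjusted over the list alone). They include the receptors NR/ETR3 (1.44 ± 0.18) and ETR4 (1.30 ± 0.24), which rose, and ETR5 (-0.81 ± 0.13), which fell, and the ripening gene E4 (3.96 ± 0.33), with no shift of the list as a whole (camera adjusted p = 0.67).

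Of 20 tested genes of carotenoid synthesis and turnover, 9 rose and 4 fell, or 12 and 7 adjusted over the list alone (camera adjusted p = 0.098, and 0.034 without JMJ6-OE replicate 1, but adjusted p = 0.74 with an estimated correlation). Genes that rose included 3 that act on the way to lycopene, with log2 fold changes of 3.54 ± 0.34 for GGPPS2, 3.67 ± 0.31 for PSY1 and 4.10 ± 0.15 for ZISO. The lycopene epsilon cyclase LCYE, which draws lycopene toward lutein, had a log2 fold change of -1.58 ± 0.17. Of 15 cell wall softening genes, 7 rose and 1 fell, also adjusted over the list alone. PG2A rose 97.5-fold (log2 6.61 ± 0.23, adjusted p = 3.1e-05), pectate lyase PL 31.1-fold (4.96 ± 0.22), the endoglucanase CEL2 19.7-fold (4.30 ± 0.35) and the beta-galactosidase TBG4 9.22-fold (3.20 ± 0.25). The list shifted upward (camera adjusted p = 0.0011, but adjusted p = 0.29 with an estimated correlation). In the wider families of cell wall enzymes, 20 of 132 genes rose and 18 fell (20 and 16 adjusted over the list alone), among them a pectate lyase 8 gene (Solyc09g091430.3, 5.06 ± 0.36) and XTH23 (16.0-fold lower), with no shift as a whole (camera adjusted p = 0.64).

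All 8 aroma genes changed, 7 upward and 1 downward, also adjusted over the list alone. The branched-chain aminotransferase BCAT1 rose 32.0-fold (adjusted p = 3.2e-05), the lipoxygenases LOXB and LOXC by 2.91 ± 0.22 and 3.95 ± 0.45 on the log2 scale, and the alcohol dehydrogenase ADH2 by 1.79 ± 0.15, from 862 ± 85.9 to 2973 ± 304 CPM. The list's shift (camera adjusted p = 6.7e-05) had an adjusted p of 0.30 with an estimated correlation. Of 8 flavonoid genes, 6 rose and none fell (7 adjusted over the list alone). Chalcone synthase CHS1, the first enzyme of the pathway, went from 1.87 ± 0.317 to 327 ± 106 CPM (log2 7.44 ± 0.31), F3H rose by 4.15 ± 0.27, FLS by 3.74 ± 0.23 and the regulator MYB12 by 2.61 ± 0.21. Camera placed the list above other genes (adjusted p = 4.4e-05, and adjusted p = 0.46 with an estimated correlation).

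Of 10 steroidal glycoalkaloid genes, 3 rose and none fell (5 adjusted over the list alone). GAME5 and GAME31, which act on the bitter alkaloid as fruit ripens, rose by 3.87 ± 0.32 and 0.98 ± 0.17. GAME18 rose by 2.25 ± 0.64 (1.59 without JMJ6-OE replicate 2), a call that held only in the fit without JMJ6-OE replicate 3 among the 6 that left out a library (adjusted p = 0.011, otherwise up to 0.11), and that limma-voom did not make (adjusted p = 0.083). Camera gave the list an adjusted p of 0.067 with all libraries, 3.4e-07 without JMJ6-OE replicate 3, and 0.028, 0.044 and 0.030 without WT replicate 1, 2 and 3. With all libraries it was 0.013 with no filter, 0.0094 with the replicate block and 0.043 with upper-quartile scaling, but adjusted p = 0.74 with an estimated correlation. In sugar metabolism 3 of 9 genes rose and 2 fell, also adjusted over the list alone. The vacuolar invertase TIV1 rose by 1.93 ± 0.38 and sucrose synthase SUS3 by 0.62 ± 0.12, while the invertase inhibitor VIF had a log2 fold change of -0.96 ± 0.19. Sucrose-phosphate synthase SPS1 rose by 0.41 ± 0.10, not called in 4 of the fits that left out a library (adjusted p up to 0.082, without JMJ6-OE replicate 2). The median of the sugar list was 0.12 and its mean -0.24, with no shift by camera (upward, adjusted p = 0.64).

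Of 78 tested genes of the photosystems, light-harvesting antennae and small Rubisco subunits, 53 fell and 3 rose (54 and 3 adjusted over the list alone), with a median log2 fold change of -1.20. RBCS-3B was 27.6-fold lower (-4.79 ± 0.20, adjusted p = 3.2e-05), the antenna proteins LHCA5 and CAB8 were 3.70-fold and 4.50-fold lower, and the photosystem I subunit PSAL 4.41-fold lower. Rubisco and antenna genes form families of close copies, between which the counting could have split reads. Camera gave an adjusted p of 2.2e-16, and an adjusted p of 0.44 with an estimated correlation.

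Of 62 ethylene response factors, 32 fell and 7 rose (33 and 9 adjusted over the list alone). The strongest by adjusted p were 3 genes with the symbol ERF5, Solyc03g093540.1 (-4.31 ± 0.16), Solyc05g052040.1 (-2.95 ± 0.13) and Solyc08g078190.1 (-3.36 ± 0.15), and ERF3 (Solyc10g006130.1, -2.78 ± 0.13). The list's downward shift had an adjusted p of 1.4e-05 by camera and an adjusted p of 0.086 with an estimated correlation, the lowest of the 23 lists. Its estimated correlation was -0.0082, below the preset 0.01, so correlation among its genes is not what weakened this call. Of 50 auxin response genes, 7 rose and 11 fell (7 and 12 adjusted over the list alone). SAUR32 (-2.82 ± 0.25) and SAUR20 (-2.58 ± 0.24) fell, and the auxin response factors ARF5 (1.14 ± 0.14) and ARF17 (1.33 ± 0.18) rose (camera adjusted p = 0.40). Pathogen response genes went both ways, 11 of 99 up and 18 down (11 and 17 adjusted over the list alone, camera adjusted p = 0.55). The thaumatin-like gene PR5K (Solyc04g081550.3, -1.80 ± 0.09), the activator PTI6 (-3.24 ± 0.27) and a chitinase 2 gene (Solyc07g009500.2, -5.71 ± 0.43) fell, and a cysteine proteinase inhibitor (Solyc09g097850.1, 1.61 ± 0.14) rose.

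Of 69 heat shock protein genes, 39 rose, 12 fell and 18 did not pass (40 and 12 adjusted over the list alone). The small heat shock proteins HSP21, HSP22.7 and HSP26.5, chaperones that hold unfolded proteins, rose by 5.49 ± 0.31, 5.65 ± 0.44 and 4.95 ± 0.32, and HSP70-8 rose by 1.92 ± 0.18. The upward shift had a camera adjusted p of 1.4e-05 and an adjusted p of 0.62 with an estimated correlation. Of 55 cytosolic ribosomal protein genes, 4 rose and 4 fell (3 and 1 adjusted over the list alone), with a median of 0.0038, a mean of -0.049 and no shift by camera (upward, adjusted p = 0.67). RPS13 had a log2 fold change of -0.79 ± 0.16 and RPS25 rose by 0.52 ± 0.11. RPL10 rose by 0.45 ± 0.10 and RPL2 by 0.51 ± 0.12, both not called without JMJ6-OE replicate 2 (adjusted p = 0.051 and 0.069), and RPL2 also not without JMJ6-OE replicate 3 or WT replicate 2 or 3 (adjusted p = 0.052, 0.053 and 0.053). In replication and cell division 10 of 73 genes rose and 7 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.77). The replication licensing factor MCM2 rose by 0.87 ± 0.10, while cyclin CYCD1-1 (-2.14 ± 0.27), a histone H1-like gene (Solyc09g083380.3, -1.07 ± 0.15) and a histone H3.v1-like gene at 1.57 ± 0.633 CPM in WT (-3.57 ± 0.49) fell.

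Marker lists of other cell types and tissues of the fruit showed no shift by camera. The cuticle list had 0 higher and 1 lower of 6 genes, the cutin synthase CD1 at -1.12 ± 0.23 (camera adjusted p = 0.67). The seed list had 2 of 13 genes higher, an oleosin 1-like gene (Solyc06g060840.1, 3.11 ± 0.41) and LEA-14 (Solyc04g078750.3, 1.00 ± 0.16, camera adjusted p = 0.47). In the xylem and lignin list 8 of 29 genes rose and 7 fell (camera adjusted p = 0.47). The cinnamoyl-CoA reductase genes Solyc02g089770.3, Solyc08g076790.3 and CCR1 rose by 3.36 ± 0.16, 3.12 ± 0.23 and 3.21 ± 0.32, and CAD9 had a log2 fold change of -1.94 ± 0.26. The first 2 share a symbol and description, and the counting may have split reads between them. In the phloem list 5 of 11 genes rose and 3 fell (camera upward, adjusted p = 0.64, median 0.30, mean -0.18). The sieve element occlusion genes Solyc03g111797.1 (3.73-fold higher) and Solyc05g013850.2 (3.27-fold higher) and the phloem protein 2 genes Solyc02g092140.1 (1.28 ± 0.18 on the log2 scale) and Solyc12g096900.2 (-1.34 ± 0.24) were called. Counts adjusted over the list alone were the same for the cuticle, seed and phloem lists, and 9 higher and 7 lower for xylem. The fry test, which asks whether the members of a list move together in one direction without comparing them with other genes, called 13 of the 23 lists. These include ethylene biosynthesis (adjusted p = 0.015), carotenoid synthesis (0.028), sugar metabolism (0.047), seed (0.0024), xylem (0.035) and auxin response (0.0035), which camera did not call.

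**Figure D3:**
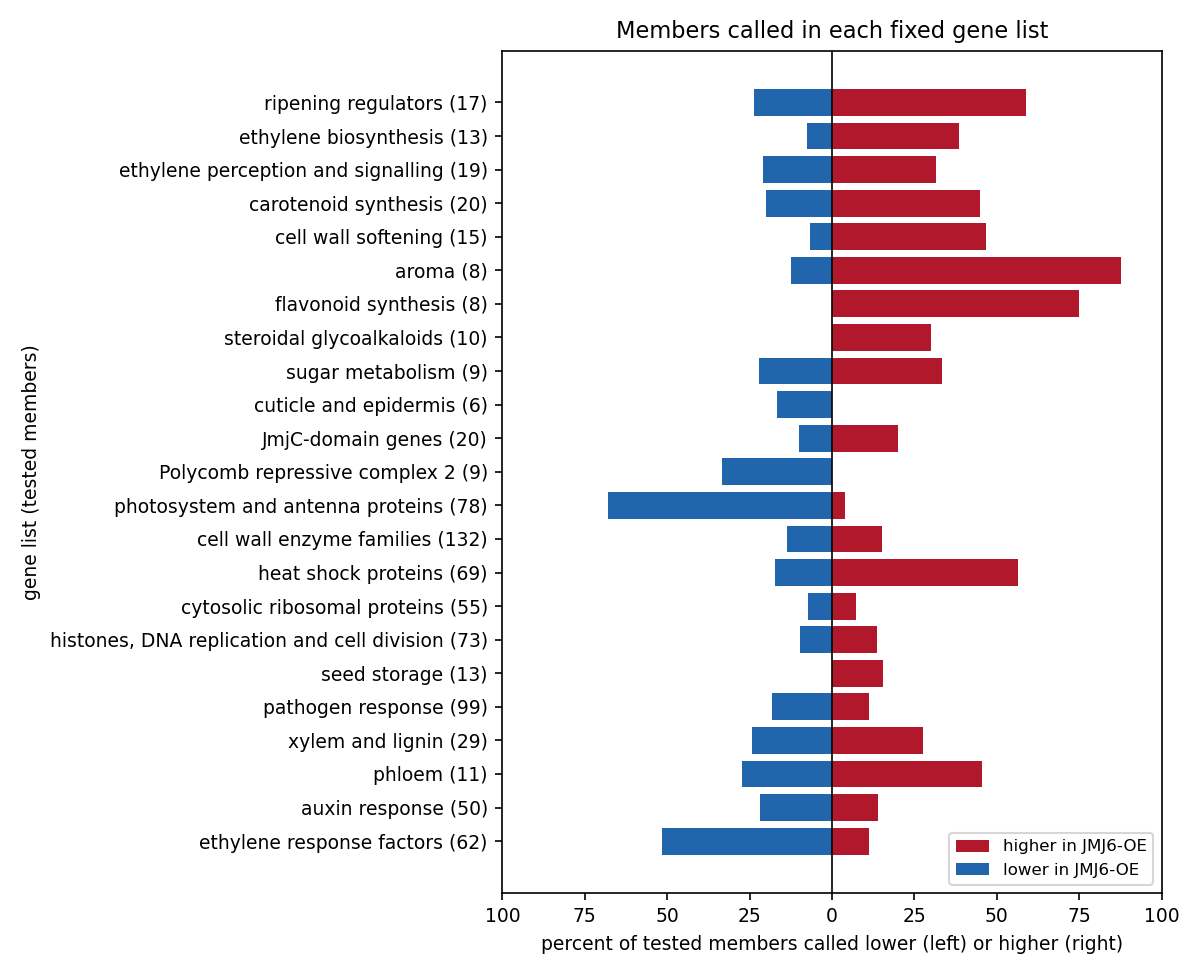
Share of the tested members of each of the 23 gene lists called higher (right) or lower (left) in JMJ6-OE by edgeR at an adjusted p under 0.05. The aroma list has the highest share of members called higher, 87.5%, and the photosystem list the highest share called lower, 67.9%.

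Among abundant genes without overlap between the groups, the largest increases belonged to genes low in WT. Transcript of the transporter gene DTX27 (Solyc04g074840.3) went from 1.03 ± 0.168 to 389.6 ± 159.8 CPM (log2 8.55 ± 0.43), and that of a histidine decarboxylase gene (HDC, Solyc08g066240.3) from 10.9 ± 2.45 to 1782 ± 477 CPM (7.36 ± 0.32). A second HDC row, Solyc08g066245.1, rose by 7.22 ± 0.35. These copies lie side by side and may share reads, so their separate values are uncertain. A glutathione transferase gene that carries the symbol HSP26-A (Solyc01g081250.3) rose by 9.26 ± 0.84 (8.58 without WT replicate 3), a fatty acid elongation gene (eloA, Solyc01g104210.2) by 8.07 ± 0.38, and an uncharacterized gene with the symbol RE1 (Solyc02g065260.3) by 7.23 ± 0.42 (8.03 without WT replicate 1), beside CHS1. Through its symbol the transferase also counts among the heat shock genes above. A proline-rich protein gene (Solyc03g116200.2) had 3 counts over the WT libraries and 2243 over the JMJ6-OE libraries, a ratio of 872 in CPM (95% exact counting interval 298 to 4232). Most of these came from JMJ6-OE replicate 1, at 60.5 CPM against 4.55 and 5.12 in replicates 2 and 3, and its call was lost without WT replicate 2 (adjusted p = 0.069) and by limma-voom (adjusted p = 0.16), while DESeq2 gave it no adjusted p. Its log2 fold change of 9.55 was 7.28 without JMJ6-OE replicate 1, 12.57 without WT replicate 2 and 8.95 without WT replicate 3.

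Of the largest decreases, that of Solyc01g059990.3, described as a homolog of serine/threonine phosphatase 7, left no counts. It had 3517, 3967 and 5243 counts in the WT libraries and 0 in each JMJ6-OE library, at least 3637-fold lower against a floor of 3 counts over the JMJ6-OE libraries. The transcription factor genes LSH4 (Solyc09g090180.1) and CBF1 (Solyc03g026280.3, symbol DREB1A) were 71.5-fold and 50.3-fold lower, the cold-response regulator CBF1 at 45.2 ± 1.84 CPM in WT and 0.882 ± 0.542 CPM in JMJ6-OE (log2 fold change -5.65 ± 0.36, and -6.25 without JMJ6-OE replicate 1). The chitinase 2 gene above was 52.5-fold lower. For 4 further genes the WT level rested mostly on replicate 3. The desaturase FAD2 (Solyc12g100250.2, -6.75 ± 1.28) stood at 88.5 CPM there, with 6.93 and 16.0 CPM in the other WT libraries. The corresponding values were 233, 12.6 and 63.1 CPM for the transporter PDR1 (-5.70 ± 1.34), 86.0, 3.75 and 7.37 for CYP71D55 (-5.82 ± 1.49), and 64.8, 3.42 and 5.79 for CYP71A6 (-5.63 ± 1.42). Without WT replicate 3 the log2 fold changes were -5.10 for FAD2, -4.32 for PDR1, -3.32 for CYP71D55 and -3.25 for CYP71A6, and that of PDR1 was -7.12 without JMJ6-OE replicate 2. Their calls were lost without JMJ6-OE replicate 1 (adjusted p from 0.056 for FAD2 to 0.11 for CYP71D55) or replicate 3 (from 0.052 to 0.10). The cytochrome P450 genes were also not called without JMJ6-OE replicate 2 (adjusted p = 0.089 and 0.086), and limma-voom called none of the 4.

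Of 122 pathways in the deposited annotation, 24 shifted against other genes by camera, 20 upward and 4 downward. The lowest adjusted p belonged to antenna proteins (23 lower and 1 higher of 29 genes, adjusted p = 5.5e-11) and photosynthesis (36 lower and 3 higher of 75, 9.3e-09). Upward shifts included the proteasome, with 32 of 53 genes higher and none lower (adjusted p = 1.5e-07), the citrate cycle (33 higher and 3 lower of 58, 7.7e-07), oxidative phosphorylation (64 higher and 14 lower of 147, 2.5e-04) and flavonoid biosynthesis (14 higher and 6 lower of 28, 0.0027). Plant hormone signal transduction (67 lower and 26 higher of 217) and plant-pathogen interaction (80 lower and 32 higher of 237) shifted downward, at adjusted p of 0.0065 and 0.0083. With an estimated correlation camera called 0 pathways, the lowest adjusted p = 0.78 with an estimated correlation, and 5 had an unadjusted p under 0.05.

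The authors' deposited table holds its own comparison. In it 3836 genes were higher and 3837 lower at a false discovery rate under 0.05, of which 1062 and 2391 by at least 2-fold. Its folds are ratios of mean FPKM. Over the genes called here they differed from the fitted ones by a median of -0.19 (log2), so the 2-fold counts are not directly comparable. Of the genes called here, 3492 of the higher and 3346 of the lower were called in the same direction in the authors' deposited table, and 0 in the opposite one. Both comparisons rest on the same libraries, so this overlap is between methods and not between experiments. DESeq2 run here called 3837 genes higher and 3839 lower, close to the authors' numbers, though their test is not given.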

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

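The estimated correlation for the pathways was added after seeing the data, and the other alternatives were fixed before. The counts of genes higher and lower stayed within 1.5 times of 3517 and 3394 under RLE and upper-quartile scaling, DESeq2, limma-voom and both filters, and no gene called in the main test was called in the opposite direction in any of these. Leaving out 1 library gave 2027 to 4169 higher and 2046 to 3962 lower genes. The lowest values came without JMJ6-OE replicate 2, and 2296 genes were higher without WT replicate 2. These fits have fewer libraries, and the cause was not tested. With the replicate number as a block, 3024 genes were higher (2887 shared) and 2964 lower (2769 shared). Same-numbered libraries did not deviate together over all genes (r = 0.064, 0.032 and -0.060). WT replicates 2 and 3 correlated best with JMJ6-OE replicates 3 and 2, but WT replicate 1 with JMJ6-OE replicate 1. With the block the adjusted p fell for some ripening genes (RIN 0.0032 to 0.00037, ACO1 0.019 to 0.0034). It rose for others (TBG4 0.00036 to 0.0025, PL 3.2e-05 to 0.00033). The numbers are not taken to pair samples, though a pairing is not excluded. Of 104 named genes called, 84 were called under every alternative that tested them and 93 under all that kept every library. Those lost with every library kept are REF6 (0.065 with upper-quartile scaling and 0.065 with the replicate block), the JMJ25 genes that rose and fell (0.068 and 0.051 with the block), JMJ706 (0.065 by DESeq2, 0.053 with no filter, 0.087 with the block), MSI1 (0.054 with the block), GAME18 (0.083 by limma-voom, 0.065 with no filter, 0.14 with the block), and Solyc03g116200.2, FAD2, CYP71D55, PDR1 and CYP71A6 by limma-voom (0.16, 0.17, 0.25, 0.14 and 0.24), the last 3 also with no filter (0.058, 0.051 and 0.052). These are adjusted p. No called named gene reversed, and 1 that was not called, the JMJ25 gene Solyc02g082400.3, was called with upper-quartile scaling (0.026). Camera called 7 of 23 lists at the preset correlation, 0 with an estimated correlation (3 had an unadjusted p under 0.05) and fry called 13. The fall to 0 cannot be put down to correlation alone, since that run also changed the degrees of freedom. The estimate was -0.0082 for ethylene response factors and 0.017 for cell wall softening, beside the preset 0.01. Pathways went from 24 called to 0 with an estimated correlation. For the lists limma-voom gave no separate value, since camera already ran on voom values, and alternatives for FPKM-only tables did not apply. The authors' deposited table counts 7673 genes, or 3453 with at least a 2-fold difference, by the stricter threshold itself. Depth limits mainly low genes, since 3 counts are 0.082 to 0.11 CPM.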

Other observations

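Tests in this part on the splits of the libraries, on gene groups outside the fixed lists, on the JMJ6 transcript, on the neighbours and chromosomes of silent genes, on the correlation between libraries and on their depth were chosen after the results were seen. That on other splits for silent genes and the bound of 0.5 for tissue markers in a library were written before their results were seen, and the spread and the split by tissue were added after. Among 30 gene groups formed from the table's descriptions, 8 shifted by camera at the preset correlation (adjusted over the 30). The groups were picked after the fold changes had been seen, and the adjustment does not cover that choice. The vacuolar proton ATPase, which acidifies the vacuole, had 18 of 26 subunits higher and 1 lower in JMJ6-OE (adjusted p = 6.7e-06). Mitochondrial electron transport and ATP synthase had 36 of 75 genes higher and 1 lower, and the proteasome 28 of 51 higher and 1 lower. Downward shifts were found for receptor-like kinases (124 lower and 28 higher of 337, adjusted p = 2.2e-04), MYB factors (19 lower and 2 higher of 50, 7.3e-04), WRKY factors (24 lower and 6 higher of 52, 0.0033) and ZAT zinc finger proteins (5 lower and 1 higher of 9, 0.022). DNA methyltransferases and argonaute 4 genes had 7 of 21 lower and none higher (adjusted p = 0.040). None of the 8 had an adjusted p below 0.46 with an estimated correlation.

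Within the glycoalkaloid list, JMJ6-OE replicate 3 differed from the other JMJ6-OE libraries. The genes given here were chosen after their values were seen, and apart from GAME5 none was called. GAME11 stood at 386 and 438 CPM in replicates 1 and 2 and at 32.6 CPM in replicate 3, against 38.4 to 52.8 CPM in WT. GAME4 stood at 33.9, 77.8 and 3.19 CPM in replicates 1, 2 and 3, and GAME12 at 201, 182 and 12.9 CPM. GAME5 was at 1849 CPM in replicate 3. Of genes reaching 10 CPM in some library, 23 were at least 4-fold below both other JMJ6-OE libraries in JMJ6-OE replicate 3, against 10 in replicate 1 and 6 in replicate 2, and 8, 6 and 3 were as far above. In WT, 30 were at least 4-fold above both other WT libraries in WT replicate 3, against 4 in replicate 1 and 1 in replicate 2, and 15, 10 and 7 lay as far below in replicates 1, 2 and 3.

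Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called as many as 6911 genes, and the highest other called 1. Every other split puts both genotypes on each side, so the genotype difference enters its spread and few calls follow from the design. The 10 splits are also too few for a share under 0.05.

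The JMJ6 transcript rose only 1.45-fold in fruit labelled as overexpressing it. The choice among TMM, RLE and upper-quartile scaling does not hide a larger increase. The largest log2 fold change under these 3 scalings was 0.54 (SE 0.12), below the value of 1 that a 2-fold rise needs. A change in total mRNA between the genotypes would escape all 3 alike and was not tested. Reads of the transgene counted at another JmjC row stay open, since among 19 rows REF6 gained 15.4 CPM (SE 2.11), beside 11.4 for JMJ6 and the 13.9 that JMJ6 lacks to a 2-fold rise. A JMJ25 gene (Solyc02g078790.3) gained 10.3 CPM, and in replicate 1 alone the ELF6-like gene Solyc04g028580.2 lay 1.67 above the WT mean on the log2(CPM + 1) scale. The rows Solyc04g028560.3 and Solyc04g028570.1, also described as ELF6, gained only 0.88 and 0.11 CPM in JMJ6-OE replicate 1. The endogenous gene may simply rise as fruit ripens, and JMJ6 CPM ordered the JMJ6-OE libraries as the distance of 41 called ripening genes from WT did (3 of 3 pairs), but 3 libraries give an exact one-sided p of 0.17 at best. A modest transgene, reads counted at another JmjC row and the endogenous rise cannot be told apart here, and a transgene without counts at any of these rows, or a wrong match of the row to JMJ6, was not tested.

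Solyc01g059990.3 had 0 counts in every JMJ6-OE library, and 9 genes were at 0 counts in all libraries of one genotype and at 30 or more in all of the other, 6 of them present in WT. The missing counts do not sit at 1 of the 180 rows searched, which were the 10 neighbouring gene models and the rows of the same description. The largest gain among them in JMJ6-OE was 2.42% of the loss. Most rows of that description had 0 counts in every library. Counting that switches between gene models without regard to genotype stays open for this 1 gene, since the other 9 splits of the libraries held up to 2 such genes each and 6 in all, although the prediction written beforehand took so low a number as excluding it. The neighbouring glucanase rows Solyc01g059965.1 and Solyc01g059980.3 held 6020 and 5 counts in WT replicate 3 and 100 and 4035 in WT replicate 1. This may be such a switch, which a split into 3 and 3 does not see. In JMJ6-OE replicates 1, 2 and 3 the first row held 10, 29 and 55 counts and the second 298, 1068 and 2200. Their gains in JMJ6-OE were -44.9% and -35.8% of the loss of Solyc01g059990.3. That of Solyc01g060030.3 was -18.5% and that of Solyc01g060040.3 -0.99%, and none of the 10 neighbouring rows gained. Whether these decreases share a cause with the silent gene was not tested. The 8 all-or-none genes with a chromosome lie on 6 chromosomes, and a variant or insertion in the transgenic plants, a silenced gene and a switch to a row outside those searched cannot be told apart without reads.

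JMJ6-OE replicate 1 lay nearest WT on the first component (56.7, against 77.7 and 89.7). Depth does not account for it, since its total of 32218345 counts lies between the 30508225 and 36299263 of the other JMJ6-OE libraries. The difference of replicate 3 from replicate 1 correlated with that of replicate 2 from WT (r = 0.37, at most 0.15 in size among WT libraries), but replicate 1 was picked on that same contrast, so the value restates the position and does not test whether the libraries stand at different points of one change. The seed, xylem and phloem lists did not rise by 0.5 (log2) in replicate 1 over the other JMJ6-OE libraries. Their medians were -0.028 (SD over members 0.40), -0.13 (SD 0.56) and -0.062 (SD 0.21). Seed material that raises its markers by 0.5 therefore does not account for the position of replicate 1. Of the xylem and phloem genes, 8 of 29 and 5 of 11 were called higher in JMJ6-OE, and 7 and 3 lower. A library nearer WT moves such genes whatever its tissue content, so these medians cannot exclude xylem or phloem material. Cuticle or epidermis material also stays open (0.037, SD 0.78). A lower content of seed, xylem or phloem material in replicate 1 was not tested. Whether the replicates are different transgenic lines, plants or harvests was not tested either.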
